A study of Homo sapiens with 6 samples.

How the data were processed

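RNA-seq values of 6 LX-2 libraries, 3 WT and 3 with an MPI exon 3 mutation, were taken from 1 table of the whole series. Per the labels' protocols, total RNA was extracted with TRIzol, mRNA was enriched by poly(A) selection, cDNA was made by random priming, and sequencing was paired-end on an Illumina HiSeq. The submitters' processing notes name Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2, DESeq2 and the GRCh38 build, without roles or settings. The annotation release, the strand setting and the treatment of multi-mapping reads are not given in the sources used here.

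Each library has 1 column of values, a signal that the authors deposited without naming its unit. In each column 100% of values were whole multiples, within 0.01 of a read, of 1 step, which is what gene counts divided by 1 size factor per library give. The steps correspond to size factors from 0.859 to 1.10 and returned whole reads for all genes. Because the authors scaled the libraries to each other, a change in total RNA per cell does not show in these values. The table also holds the authors' deposited log2 fold change and the authors' deposited p-value and adjusted p-value per gene. The adjusted values equal a Benjamini-Hochberg adjustment of the p-values over the listed genes. These columns served only as an alternative.

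The table lists 17911 genes, with a lowest mean of 9.83 over the 6 libraries, so genes of lower level are not analysed here. Gene symbols stored as dates (22) were replaced through the Ensembl ID with GENCODE release 29, a release chosen here, which holds 17828 of the IDs and lacks 83. Coordinates are those of that annotation on GRCh38. Recovered reads per library were 27037905 to 34970840 over the listed genes, so a level of 100 rests on about that many reads per library. A count of 3 reads corresponds to a value of 2.72 to 3.49, depending on the library. A group with 3 or fewer reads of a gene is given as a ratio with an exact Poisson interval, which covers counting error only.

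Libraries of a genotype were compared first. The chi-square per gene between replicates was 3.51 to 16.8 in WT and 2.73 to 35.2 in the mutant, more than counting noise gives, so no libraries were merged as repeat sequencing of 1 library, and the library numbered 1 stood apart in both genotypes. The labels number the libraries 1 to 3 in both genotypes. Deviations from the genotype means correlated across genes between same-numbered libraries at 0.545, 0.189 and 0.276, all above the limit of 0.1, so the numbers were taken to pair the libraries, from the data and not from a stated batch. Unlike-numbered libraries passed that limit too: WT replicate 3 with mutant replicate 2 (0.299) and WT replicate 2 with mutant replicate 3 (0.168). Deviations from the mean of 3 libraries offset each other, so the likeness of the libraries numbered 1 alone pushes the others to correlate. The values thus show that the libraries numbered 1 share a deviation, but not that numbers 2 and 3 mark pairs. The blocked fit is an alternative and its values stand beside results whose call it changes.

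Before the data were examined, edgeR's quasi-likelihood test was fixed for raw counts and limma-trend for values divided by size factors. The table held the latter, so the main test was limma-trend. It was run with limma 3.58.1 (trend and robust) in R 4.3.3 on log2(value + 1) for the 17893 genes with a mean of at least 10, with genotype as the only term and Benjamini-Hochberg adjusted p under 0.05. Fold changes on this scale understate changes of genes with low values. Gene lists (36) were fixed at the same time and tested with camera at a preset inter-gene correlation of 0.01 against all other tested genes, with adjustment over the 35 lists of at least 5 tested members. None of the 6 calls held with a correlation estimated per list. For cholesterol synthesis that estimate was 0.00933, below the preset, so a higher correlation is not what ended its call. Camera with both the replicate block and an estimated correlation gave an adjusted p of 0.867 for each of the 6. That run is left out of the ranges given below over the camera alternatives. Genes are named by a rule fixed then too: MPI, the 10 largest rises and 10 largest falls among genes past the test with a mean of at least 100 in the higher genotype, no overlap between libraries and a gene symbol, and in each list up to 4 changed members of largest change with that mean, or the most abundant unchanged one. Of these, mainly genes whose calls held under all alternatives are named, a choice made after the alternatives were run, and DLC1 and PMVK, outside the rule, were named after their values were seen. Some genes that the rule selects are not reported here.

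Alternatives fixed beforehand were a replicate block, leaving out each library, TMM or upper-quartile rescaling, no filter or a mean of at least 50, pseudocounts of 0.5 and 5, DESeq2 1.42.0 on the recovered reads, the authors' columns, an adjusted p under 0.01, an absolute log2 fold change of at least 1, camera with an estimated correlation, and fry. Counted as added after the data were examined were edgeR 4.0.16 on recovered reads with and without the block (2995 rises and 2872 falls without it), fry with the block, and leaving out both libraries numbered 1. The plan had, however, named the count test on recovered reads as an alternative, which covers edgeR without the block.

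The tests were checked on simulated counts drawn from these libraries with 200 changed genes. In these counts limma-trend (17480 genes) recovered 36% of changes of 0.5 and 65% of changes of 1 on the log2 scale, and 7.02% of its calls were false. With the replicate block it recovered 32% and 61%, with 12.7% false. The simulated counts held no replicate effect, so they cannot show what the block gains where replicates differ. edgeR (17557 genes) recovered 38% and 65% with 7.69% false, and DESeq2 (17911 genes) 56% and 71% with 23.3% false. The real comparison called 5829 genes, far more than were changed in the simulation. The cutoff of the adjustment depends on that number, so these shares describe the simulation and not the real comparison. With the preset and with the estimated correlation alike, the list test called the 1 simulated list that was moved (by -0.4 on the log2 scale) and 0 of 34 others. Simulated genes were drawn independently of each other. This check therefore cannot show how either setting does for lists whose members vary together. Figures were drawn with matplotlib 3.10.9. Genes with near-identical copies, and overlapping or antisense genes, are uncertain because the counting settings are not known. The position tests were restricted to autosomes.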

Results

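RNA from LX-2 cells, an immortalised human hepatic stellate cell line that serves as a culture model of the liver's matrix-producing cells, was sequenced in 2 genotypes, with 3 libraries each. One genotype was wild type (WT) and the other carried a mutation in exon 3 of MPI (mutant). MPI encodes mannose phosphate isomerase, which interconverts fructose 6-phosphate and mannose 6-phosphate at the entry to the mannose pathway of protein glycosylation. The comparison of the genotypes asks which transcripts differ in level when MPI is mutated. Reads recovered from the values over the listed genes were 33991848, 27037905 and 30215594 in the WT libraries and 33622460, 34970840 and 31966756 in the mutant libraries. Levels below are normalised read counts, given as mean ± SD (n = 3 libraries per genotype), and log2 fold changes are mutant over WT on the log2(value + 1) scale with their SE. Nothing in the labels says that the libraries of a genotype came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

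The genotypes separated on the first principal component, which held 71.8% of the variance. The second component, with 15.9%, set the library numbered 1 of each genotype apart from those numbered 2 and 3.

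**Figure D1:**
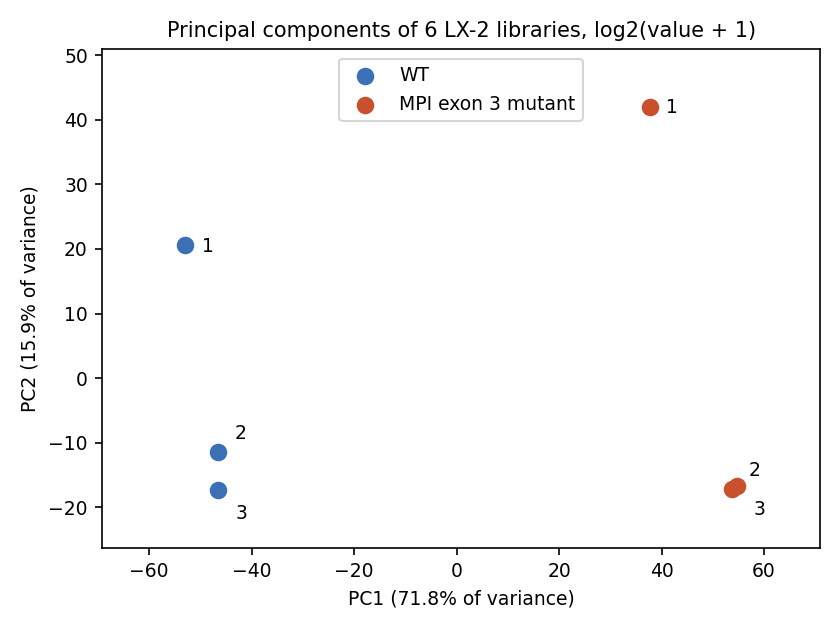
Each point is 1 library, placed by its first (x axis) and second (y axis) principal component of log2(value + 1), with the percent of variance on the axes, coloured by genotype and numbered by replicate. WT libraries lie between -53.0 and -46.5 on the first component and mutant libraries between 37.7 and 54.7.

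MPI itself (ENSG00000178802, GRCh38 chromosome 15, 74890005 to 74902219, plus strand) was present in all libraries of both genotypes. Its level was 1292, 1283 and 1256 in the WT libraries and 1051, 978 and 1035 in the mutant libraries, a log2 fold change of -0.32 ± 0.07 (limma adjusted p = 0.00648). The labels do not say which transcript numbers the exons. In MPI-202, a transcript of 8 exons chosen here from GENCODE 29, exon 3 lies at 74891379 to 74891579 and is 201 bp long. The counts cover the whole gene, so they do not show which sequence the exon carried.

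The mutant cells differed from WT in 5829 of 17893 tested genes, of which 2866 rose and 2963 fell (limma-trend, adjusted p under 0.05). With the replicate block, 4494 rose and 4410 fell, of which 2864 and 2960 were among the genes above. Leaving out 1 library moved the number of rises by over 1.5 times for WT replicate 2 (1865), mutant replicate 1 (4389), mutant replicate 2 (1738) and mutant replicate 3 (1817). With both libraries numbered 1 left out, a choice made after the data were examined, 4984 rose and 4758 fell.

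HAS2, a hyaluronan synthase, rose from 83.3 ± 19.8 to 2290.1 ± 834, and VCAN, the hyaluronan-binding proteoglycan versican, rose from 458 ± 63.3 to 8409 ± 2676. Their log2 fold changes were 4.72 ± 0.29 and 4.16 ± 0.20 (limma adjusted p = 1.72e-05 and 6.07e-06). HGF, the hepatocyte growth factor, rose from 7.51 ± 1.96 to 241 ± 21.0, and CCL7, a monocyte chemoattractant, from 5.33 ± 2.39 to 136 ± 47.1. HSD11B1, which regenerates active cortisol, had 2 reads in the WT libraries together and 443 in the mutant libraries, a ratio of 206 with an exact Poisson 95% interval from 56.7 to 1706 that covers counting error only. The remaining genes among the 10 largest rises were the homeobox gene PKNOX2 (6.35 ± 0.26), the surface glycoprotein gene CD24 (4.92 ± 0.23), ELMOD1 (4.16 ± 0.20), the transcription factor EGR2 (4.15 ± 0.26) and SYT7 (4.12 ± 0.27), with limma adjusted p from 3.33e-06 to 2.27e-05. With a pseudocount of 5, PKNOX2 was 5.47, and CCL7 was 3.74 where the fit had given 4.46 ± 0.37. CCL7 was 3.85 with both libraries numbered 1 left out. CD24 has near-identical copies elsewhere in the genome, so its count is uncertain.

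ADAMTS5, an aggrecan- and versican-cleaving protease, had the largest fall, from 296 ± 28.6 to 1.98 ± 2.05 (-6.92 ± 0.52, limma adjusted p = 4.27e-05). RSAD2, an interferon-induced antiviral gene, fell from 187 ± 67.5 to 2.18 ± 3.02, and MGMT, a DNA repair methyltransferase, from 199 ± 6.86 to 4.42 ± 2.80. FBLN1, the matrix protein fibulin-1, fell from 224 ± 5.79 to 3.51 ± 1.03, and the cation channel gene TRPC4 from 368 ± 61.0 to 5.41 ± 1.83. The other 5 of the 10 largest falls were CLSTN2 (-6.10 ± 0.71), OCIAD2 (-5.62 ± 0.45), TMEM246 (-5.55 ± 0.42), CADM3 (-5.45 ± 0.25) and PALM (-5.34 ± 0.19), with limma adjusted p from 1.61e-06 to 4.13e-04. These fitted sizes depend on the pseudocount, because the mutant libraries held only 6 to 25 reads of these genes in total, and some moved by over 1.5 times when 1 mutant library was left out. With a pseudocount of 5, ADAMTS5 was -5.47, TRPC4 -5.16, RSAD2 -4.76, FBLN1 -4.75, CLSTN2 -4.73, CADM3 -4.60, TMEM246 -4.50, OCIAD2 -4.48 and MGMT -4.48. ADAMTS5 was -6.28 without replicate 2, RSAD2 -7.02 without replicate 2 and -5.65 without replicate 3, and CLSTN2 -6.81 without replicate 1 and -5.36 without replicate 3. The calls of these 20 genes were kept under every alternative in which the gene was tested.

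**Figure D2:**
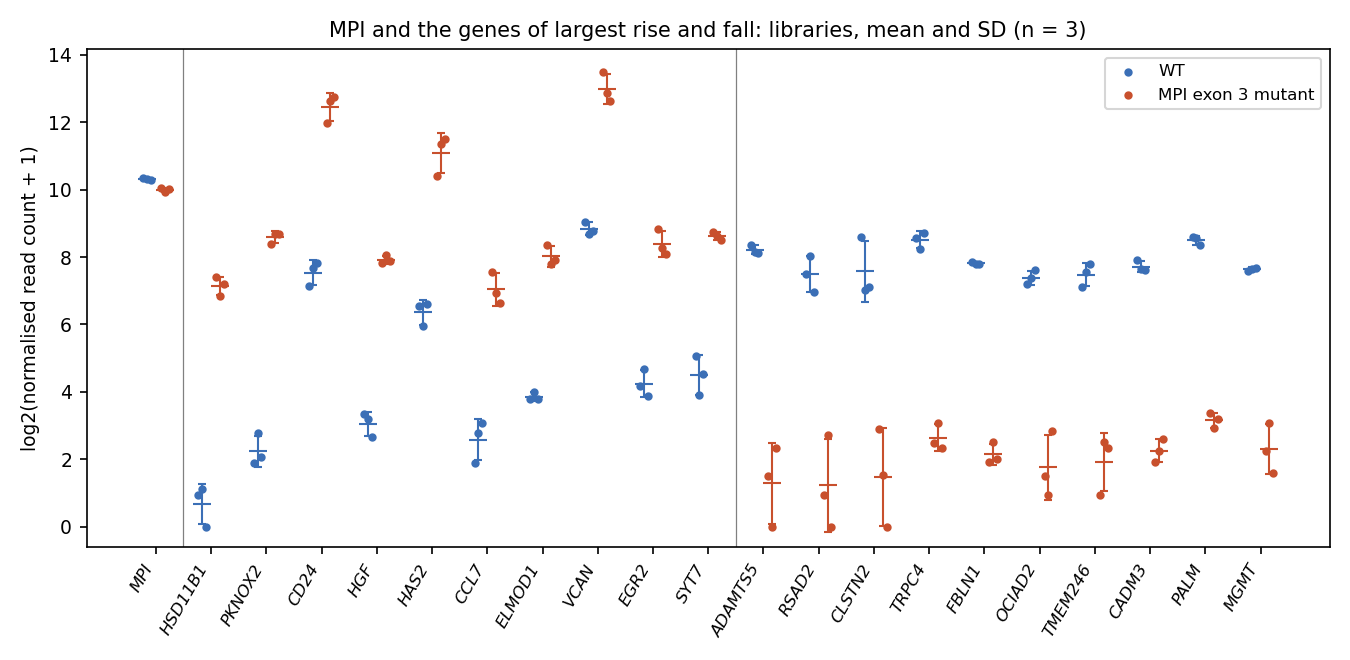
For MPI (left) and the genes of the 10 largest rises (middle) and 10 largest falls (right), points are single libraries, the bar is their mean and the whiskers 1 SD (n = 3) on a log2(normalised read count + 1) axis. The libraries of the genotypes do not overlap for any of these genes, as the rule that chose all but MPI required.

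Of 36 fixed gene lists, 35 had at least 5 tested members, and 6 differed from the other genes with camera at the preset correlation of 0.01. Interferon-stimulated genes, interferon signalling's antiviral effectors and sensors, fell as a group: 0 rose and 18 fell of 24 measured members (0 and 19 adjusted over the list alone), with a median log2 fold change of -1.26 (camera adjusted p = 7.48e-10). The adjusted p was 0.429 with an estimated correlation. OASL fell from 254 ± 103 to 10.5 ± 2.97, IFIT2 from 1129 ± 241 to 223 ± 42.7 and IFI44 from 653 ± 165 to 141 ± 16.8 (limma adjusted p = 4.05e-05, 4.24e-05 and 6.32e-05).

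Targets of the mechanosensitive coactivators YAP and TAZ also fell: 1 rose and 14 fell of 21 measured members (1 and 17 adjusted over the list alone), with a median of -0.53 (camera adjusted p = 2.52e-06). With an estimated correlation the adjusted p was 0.429. CRIM1 fell from 16148 ± 886 to 7515 ± 237, RBMS3 from 1508 ± 86.4 to 613 ± 53.2, and TGFB2, which encodes a TGF-beta ligand and stands on the TGF-beta list too, from 1362 ± 343 to 436 ± 60.7. IGFBP3, an insulin-like growth factor binding protein on 3 of the lists, fell from 1060.0 ± 260.0 to 162 ± 54.1 (-2.72 ± 0.25, limma adjusted p = 1.26e-04). The member that rose was DLC1, from 7049 ± 518 to 11062 ± 222.

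Genes of the G1/S transition and DNA replication were lower: 2 rose and 19 fell of 25 measured members (2 and 19 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 3.68e-06). The adjusted p was 0.429 with an estimated correlation. The cyclin gene CCNE2 fell from 847 ± 33.2 to 452 ± 30.4. The 2 members that rose were the cyclin genes CCND1, from 12752 ± 1169 to 31358 ± 7827 (1.27 ± 0.18, limma adjusted p = 9.95e-04), and CCNE1, from 243 ± 4.99 to 478 ± 29.8 (0.97 ± 0.09, limma adjusted p = 1.48e-04). The replication helicase gene MCM7 measured 12194 ± 171 in WT and 11925 ± 778 in mutant libraries (limma adjusted p = 0.745). Among G2/M and mitosis genes 2 rose and 4 fell of 25 measured members (2 and 4 adjusted over the list alone), while 6 rose and 6 fell with the replicate block (camera adjusted p = 0.849). The mitotic kinesin gene KIF20A fell from 10116 ± 675 to 6639 ± 1040.0 and the phosphatase gene CDC25C from 1093 ± 68.8 to 743 ± 72.2. BIRC5 and AURKA rose, with log2 fold changes from 0.40 to 0.63 and from 0.35 to 0.56 over the alternatives.

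Cholesterol synthesis genes fell: 1 rose and 15 fell of 24 measured members (1 and 16 adjusted over the list alone), with a median of -0.40 (camera adjusted p = 6.17e-06). With an estimated correlation the adjusted p was 0.263, although the estimate (0.00933) was below the preset of 0.01. HMGCS1, an early enzyme of the pathway, fell from 7664 ± 373 to 4228 ± 749 (-0.87 ± 0.12, limma adjusted p = 7.97e-04), and STARD4, a sterol transfer protein gene, fell from 4014 ± 395 to 2369 ± 383. The member that rose was PMVK, an enzyme early in the pathway, from 535 ± 66.7 to 702 ± 51.6. FDPS measured 3842 ± 383 in WT and 3588 ± 262 in mutant libraries (limma adjusted p = 0.443). In fatty acid synthesis and oxidation, 3 rose and 6 fell of 24 measured members (3 and 6 adjusted over the list alone) (camera adjusted p = 0.582). The desaturase genes FADS2 and FADS1 fell from 15070.2 ± 1071 to 6455 ± 1384 and from 10796 ± 1237 to 5715 ± 690.3. They overlap in the annotation, and the strand setting of the counting is not given in the sources used here, so reads cannot be assigned with certainty between them. CPT1A, which carries fatty acids into oxidation, rose from 3486 ± 293 to 4912 ± 652.

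Mitochondrially encoded genes were higher as a group: 7 rose and 0 fell of 13 measured members (7 and 0 adjusted over the list alone), with a median of 0.25 (camera adjusted p = 0.0297). The adjusted p was 0.819 with an estimated correlation and ranged from 0.00118 to 0.819 over the camera alternatives. It was 0.171 without WT replicate 2 and 0.152 without mutant replicate 1, and nuclear copies of these genes make single counts uncertain. Between the genotypes, the median log2 fold change was -0.13 over 196 sense intronic genes and -0.06 over 1296 antisense genes, against 0.0091 over protein-coding genes. Among nuclear genes of the respiratory chain 2 rose and 4 fell of 26 measured members (2 and 2 adjusted over the list alone), while 12 rose and 4 fell with the replicate block (camera adjusted p = 0.433). Its adjusted p became 0.0346 without mutant replicate 1, in a range over the camera alternatives from 0.0346 to 0.893. COX5A rose from 1945 ± 56.0 to 2525 ± 256 and NDUFV1 fell from 5936 ± 73.6 to 4788 ± 30.2.

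Genes of the extracellular matrix moved both ways. Of matrix glycoproteins and proteoglycans, 7 rose and 14 fell of 30 measured members (7 and 14 adjusted over the list alone), with a median of -0.33 (camera adjusted p = 0.0461). This adjusted p became 0.0548 with the replicate block, 0.810 with an estimated correlation, 0.0562 without WT replicate 2 and 0.114 without mutant replicate 3, in a range over the camera alternatives from 0.00589 to 0.810. POSTN, the matricellular protein periostin, fell from 161 ± 81.3 to 4.75 ± 1.71 (-4.75 ± 0.38, and -4.00 with a pseudocount of 5), and EFEMP1 from 1055 ± 64.1 to 378 ± 65.4, against the rise of VCAN. SPARC measured 26566 ± 946 in WT and 27964 ± 3922 in mutant libraries (limma adjusted p = 0.664). Of the collagens, 3 rose and 8 fell of 22 measured members (3 and 9 adjusted over the list alone) (camera adjusted p = 0.270). For the collagens it was 0.0129 without mutant replicate 1, in a range over the camera alternatives from 0.0117 to 0.893. COL6A3 rose from 12878 ± 804 to 41258 ± 10366, COL12A1 fell from 26866 ± 3216 to 11810.2 ± 2919 and COL11A1 fell from 248 ± 121 to 15.9 ± 9.75. COL1A1, a chain of the main fibrillar collagen, measured 36688 ± 1605 in WT and 43863 ± 12042 in mutant libraries and did not pass the test (limma adjusted p = 0.329). COL1A2, the gene of the other chain, fell, with a log2 fold change of -1.37 that ranged from -1.86 to -1.03 over the alternatives.

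Of collagen processing and crosslinking genes, 7 rose and 5 fell of 23 measured members (7 and 5 adjusted over the list alone), and the list's median (-0.02) and mean (-0.13) lay below 0 while camera's direction was up (adjusted p = 0.849). ADAMTS2, the procollagen N-proteinase, fell from 326 ± 41.9 to 78.2 ± 4.75, the collagen chaperone gene SERPINH1 fell from 4058 ± 95.9 to 2457 ± 112, and the lysyl hydroxylase gene PLOD3 rose from 2272 ± 74.3 to 3491 ± 159.8. Of matrix proteases and their inhibitors, 14 rose and 6 fell of 29 measured members (14 and 7 adjusted over the list alone). Their camera adjusted p was 0.148, and 5.85e-04 with DESeq2 on recovered reads, in a range over the camera alternatives from 5.85e-04 to 0.429. The gelatinase gene MMP2 rose from 1469.5 ± 186 to 8068 ± 512 (2.46 ± 0.10, limma adjusted p = 3.02e-06) and the collagenase gene MMP1 from 608 ± 118 to 6437 ± 3767, with a log2 fold change of 3.17 ± 0.48 that became 3.83 without mutant replicate 1. TIMP3, a protease inhibitor, fell from 4538 ± 651 to 1585 ± 377.

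Markers of stellate cell state moved both ways. Of activation and contractile genes, 5 rose and 9 fell of 24 measured members (5 and 11 adjusted over the list alone) (camera adjusted p = 0.426). THY1, a fibroblast surface marker, fell from 461 ± 18.8 to 15.1 ± 5.99 (-4.92 ± 0.28, limma adjusted p = 1.36e-05), and the smooth muscle genes ACTG2 and TAGLN fell from 499 ± 193 to 111 ± 17.0 and from 3806 ± 905 to 1570.5 ± 357. FAP, the fibroblast activation protein, rose from 39.5 ± 3.17 to 339.7 ± 85.3 (3.05 ± 0.19, limma adjusted p = 1.68e-05). Of quiescence and lipid storage genes, 4 rose and 5 fell of 22 measured members (6 and 6 adjusted over the list alone), while 7 rose and 6 fell with the replicate block (camera adjusted p = 0.697). HGF and the transcription factor gene GATA6 rose, the latter from 26.3 ± 10.2 to 347 ± 64.8, and the retinoid receptor gene RXRA fell from 1445 ± 4.31 to 803 ± 4.53.

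Early targets of TGF-beta did not pass at the preset correlation: 9 rose and 5 fell of 23 measured members (9 and 5 adjusted over the list alone), with a median of 0.36 (camera adjusted p = 0.0512). The list passed with the replicate block (adjusted p = 0.0112), under which 14 rose and 5 fell, and without WT replicate 3 (0.0425) or mutant replicate 2 (0.0463). It also passed with upper-quartile rescaling (0.0466), DESeq2 (9.08e-04), edgeR (9.47e-04), edgeR with the block (3.65e-07) and both libraries numbered 1 left out (0.0279), but not with an estimated correlation (0.429), in a range over the camera alternatives from 3.65e-07 to 0.429. INHBA, which encodes an activin subunit, rose from 343 ± 96.5 to 4959 ± 1748, LTBP1, a binding protein of latent TGF-beta, from 1623 ± 83.7 to 9598 ± 1012, and PMEPA1, a feedback inhibitor of the pathway, from 88.1 ± 6.72 to 532 ± 51.7. Of NF-kB and senescence-associated cytokines, 11 rose and 6 fell of 27 measured members (12 and 6 adjusted over the list alone) (camera adjusted p = 0.194). With edgeR on recovered reads the list's adjusted p was 0.164, and 0.00192 with the replicate block added, in a range over the camera alternatives from 0.00192 to 0.810. IL1B rose from 913 ± 241 to 6806 ± 1788 and CCL2 from 137 ± 22.4 to 1186 ± 547, whereas CCL5 fell from 158 ± 32.6 to 19.5 ± 9.39. IL1B was also lower in the libraries numbered 1 than in the others of their genotype, by a log2 difference of -0.72 (limma adjusted p = 4.75e-07).

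In the pathway that MPI belongs to, changes went both ways. Of mannose and GDP-sugar synthesis genes, 4 rose and 4 fell of 20 measured members (5 and 4 adjusted over the list alone), while 8 rose and 5 fell with the replicate block (camera adjusted p = 0.697). PMM2, which converts the product of MPI onward, rose from 636 ± 43.5 to 898 ± 38.3 (0.50 ± 0.08, limma adjusted p = 0.00235), DPM1, a dolichol-phosphate mannose synthase subunit, from 1960.2 ± 174 to 2819.8 ± 433, and the GDP-fucose transporter gene SLC35C1 from 593 ± 54.3 to 1030.3 ± 158. PGM1 fell, with log2 fold changes from -0.50 to -0.38 over the alternatives, and MPI itself counts among the falls. UGP2 measured 3812 ± 243 in WT and 3787 ± 246 in mutant libraries (limma adjusted p = 0.939). Of the hexosamine pathway and O-GlcNAc cycling, 4 rose and 1 fell of 17 measured members (4 and 1 adjusted over the list alone), while 6 rose and 5 fell with the replicate block (camera adjusted p = 0.582). GFPT2, which starts the pathway, rose from 1923 ± 192 to 3056 ± 115, and OGT fell, with log2 fold changes from -0.71 to -0.40 over the alternatives. With fry, which tests a list against no change, the hexosamine list's adjusted p was 0.00185, and 0.0392 in the blocked fit. Fry gave 0.619 (blocked 0.0206) for mannose and GDP-sugar synthesis and 0.367 (blocked 0.318) for lipid-linked oligosaccharides. Of lipid-linked oligosaccharide assembly and transfer, 5 rose and 1 fell of 32 measured members (4 and 1 adjusted over the list alone), while 9 rose and 2 fell with the replicate block (camera adjusted p = 0.433). There NUS1 rose from 2776 ± 29.6 to 3896 ± 383 and MAGT1 fell from 5309 ± 266 to 4300.1 ± 156.

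N-glycan processing and branching genes split: 8 rose and 4 fell of 30 measured members (9 and 4 adjusted over the list alone), with a median (-0.01) and mean (-0.01) below 0 and camera's direction up (adjusted p = 0.732). The Golgi mannosidase gene MAN2A1 fell from 3618 ± 331 to 1913 ± 249, the glucosidase II gene GANAB fell from 21678 ± 1131 to 15388 ± 355, and B4GALT3 rose from 889 ± 86.1 to 1163 ± 49.9. In glycolysis 6 rose and 4 fell of 23 measured members (7 and 4 adjusted over the list alone) (camera adjusted p = 0.697). The lactate exporter gene SLC16A3 rose from 12082 ± 990.1 to 20207 ± 2212 and the hexokinase gene HK2 from 2998 ± 222 to 4345 ± 434, while TPI1 fell from 36825 ± 2108 to 28535 ± 1828 and PKM measured 92301 ± 5941 in WT and 94010.0 ± 4607 in mutant libraries (limma adjusted p = 0.835). In the pentose phosphate pathway 2 rose and 2 fell of 11 measured members (2 and 2 adjusted over the list alone), while 2 rose and 5 fell with the replicate block (camera adjusted p = 0.697), and H6PD, its enzyme in the endoplasmic reticulum, rose from 3459 ± 290.4 to 6559 ± 838. With fry the pathway's adjusted p was 0.547, and 0.0257 in the blocked fit.

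Stress-related lists did not pass camera. With fry, which tests a list against no change and not against other genes, the adjusted p was 0.0498 for the unfolded protein response, 0.0422 for ATF4 and 0.00236 for p53 targets, and in the blocked fit 0.0721, 0.0450 and 0.0373. For the unfolded protein response and ER chaperones, 2 rose and 4 fell of 23 measured members (2 and 4 adjusted over the list alone), while 2 rose and 8 fell with the replicate block (camera adjusted p = 0.398), and the stress sensor gene ERN1 rose from 596 ± 8.64 to 767 ± 25.3. DNAJB11, HYOU1 and PDIA3 fell, with log2 fold changes from -0.34 to -0.24 over the alternatives. For ATF4 and the amino acid response, 9 rose and 3 fell of 22 measured members (11 and 3 adjusted over the list alone) (camera adjusted p = 0.154). SLC7A5, a subunit of a large neutral amino acid transporter, fell from 1315 ± 308 to 45.2 ± 12.5 (-4.85 ± 0.23, limma adjusted p = 5.60e-06), and CHAC1 rose from 181 ± 13.4 to 319.9 ± 30.5. For p53 targets, 2 rose and 11 fell of 26 measured members (3 and 11 adjusted over the list alone), while 4 rose and 12 fell with the replicate block (camera adjusted p = 0.148), and the receptor gene EDA2R fell from 208 ± 31.2 to 27.8 ± 5.19. For hypoxia targets, 5 rose and 3 fell of 21 measured members (5 and 3 adjusted over the list alone), while 7 rose and 6 fell with the replicate block, with a median of -0.04, a mean of 0.21 and camera's direction up (adjusted p = 0.697). VEGFA, the angiogenic growth factor, rose from 1732 ± 75.4 to 5174 ± 346 (1.58 ± 0.07, limma adjusted p = 4.93e-06). For NRF2 targets, 6 rose and 6 fell of 19 measured members (6 and 6 adjusted over the list alone), with a median of -0.13, a mean of 0.13 and camera's direction down (adjusted p = 0.833). The heme oxygenase gene HMOX1 rose from 706 ± 49.2 to 1449 ± 110.2.

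Among integrins 3 rose and 6 fell of 15 measured members (3 and 6 adjusted over the list alone) (camera adjusted p = 0.617): ITGA2 rose from 2233 ± 407 to 5154 ± 221, and ITGA11 and ITGB4 fell from 410.3 ± 70.9 to 182 ± 19.9 and from 993 ± 30.6 to 471 ± 50.3. Among Wnt signalling genes 6 rose and 5 fell of 18 measured members (6 and 5 adjusted over the list alone), with a median of -0.09, a mean of -0.10 and camera's direction up (adjusted p = 0.760). The receptor gene FZD8 rose from 345 ± 40.2 to 781 ± 139 and the secreted inhibitor gene SFRP1 fell from 15907 ± 3386 to 7837 ± 3044. Among growth factors and their receptors 4 rose and 9 fell of 26 measured members (4 and 10 adjusted over the list alone) (camera adjusted p = 0.148). It became 0.00470 with DESeq2 on recovered reads, in a range over the camera alternatives from 0.00470 to 0.639. PDGFB, a stellate cell mitogen, fell, with a log2 fold change of -3.01 ± 0.10 (limma adjusted p = 1.36e-06), IGF2 fell from 137 ± 19.1 to 12.2 ± 1.93, and EGFR measured 7272 ± 664 in WT and 7580.4 ± 412 in mutant libraries (limma adjusted p = 0.607).

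No list of markers of other cell types passed camera, and many of their members were not among the tested genes. With fry, the adjusted p was 0.0406 for cholangiocyte and epithelial, 0.0406 for endothelial and 0.0364 for neuronal and glial markers, and in the blocked fit 0.0373, 0.0738 and 0.0691. Hepatocyte markers had 2 tested members, too few for the list test, of which SERPINA1 fell from 163 ± 9.23 to 79.2 ± 22.6. Of cholangiocyte and epithelial markers, 2 rose and 1 fell of 7 measured members (2 and 1 adjusted over the list alone), while 3 rose and 2 fell with the replicate block, with a median of -0.18, a mean of 0.26 and camera's direction up (adjusted p = 0.697). There SOX9 rose from 1777 ± 103 to 2845 ± 256. Of endothelial markers, 2 rose and 1 fell of 8 measured members (2 and 1 adjusted over the list alone), while 2 rose and 2 fell with the replicate block, with a median of 0.07, a mean of -0.04 and camera's direction up (adjusted p = 0.697). PECAM1 rose from 29.3 ± 0.387 to 123 ± 9.36 and TEK from 96.4 ± 8.42 to 433 ± 103, and FLT1 fell from 194 ± 15.6 to 10.5 ± 3.96. Of macrophage and lymphocyte markers, 4 rose and 1 fell of 6 measured members (4 and 1 adjusted over the list alone), with a median of 0.83 (camera adjusted p = 0.433). CD14, the member that fell, went from 427 ± 41.1 to 129 ± 5.51, while CD68 rose, with log2 fold changes from 0.53 to 0.98 over the alternatives. Of neuronal and glial markers, 1 rose and 4 fell of 8 measured members (1 and 4 adjusted over the list alone), while 3 rose and 4 fell with the replicate block (camera adjusted p = 0.433), and L1CAM fell from 10803 ± 706 to 5046 ± 987. Of other mesenchymal markers, 1 rose and 2 fell of 7 measured members (1 and 2 adjusted over the list alone), while 1 rose and 1 fell with the replicate block (camera adjusted p = 0.697), and KCNJ8 rose from 90.4 ± 16.5 to 331 ± 15.9.

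Some of the genes above lie in 1 of the 25 of 233 autosomal stretches of about 50 neighbouring genes whose median log2 fold change was at least 0.3 in size, a limit chosen after the values were seen. HGF (median of its stretch 0.49) and PLOD3 (0.38) on chromosome 7, NUS1 on chromosome 6 (0.38), SLC16A3 on chromosome 17 (0.38) and CCNE1 on chromosome 19 (0.46) rose with their stretch. Their own log2 fold changes were 4.86 (HGF), 0.62 (PLOD3), 0.48 (NUS1), 0.74 (SLC16A3) and 0.97 (CCNE1). KIF20A and CDC25C on chromosome 5 (-0.31), TPI1 on chromosome 12 (-0.32), and GANAB, FADS1 and FADS2 (-0.30), NDUFV1 (-0.44) and SERPINH1 (-0.51) on chromosome 11 fell with theirs. Own log2 fold changes were -0.62 (KIF20A), -0.56 (CDC25C), -0.37 (TPI1) and -0.49 (GANAB). For FADS1, FADS2, NDUFV1 and SERPINH1 they were -0.92, -1.24, -0.31 and -0.72. SYT7 rose in the stretch of GANAB, CCND1 and CPT1A rose in that of NDUFV1, and MCM7, which did not pass, lies in that of PLOD3. COL1A2 fell in a stretch of chromosome 7 with a median of 0.33.

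**Figure D3:**
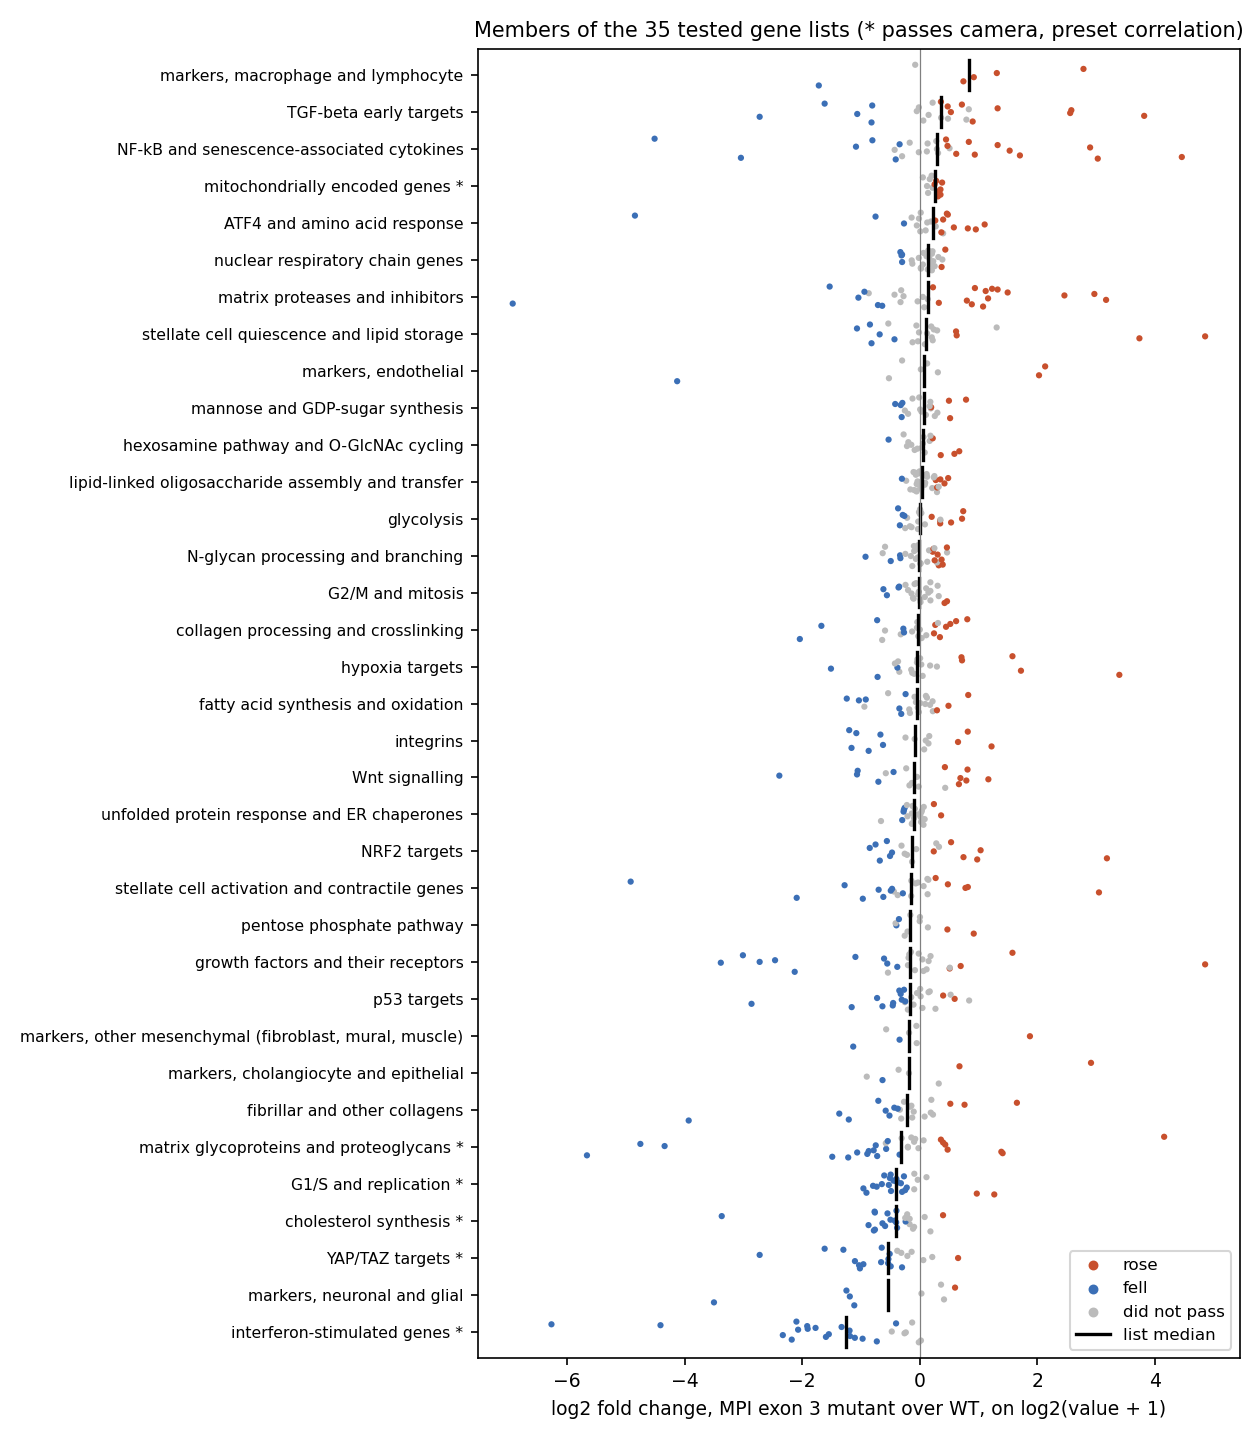
Each point is 1 tested member of 1 of the 35 tested lists, placed by its log2 fold change (x axis, mutant over WT) and coloured by whether it rose, fell or did not pass (limma adjusted p), and the black bar is the list's median. An asterisk marks the 6 lists that passed camera with the preset correlation, with medians from -1.26 (interferon-stimulated genes) to 0.25 (mitochondrially encoded genes), none of which passed with an estimated correlation.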

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

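Counted as chosen only after the data were seen were the alternatives with edgeR, with fry in the blocked fit and with both libraries numbered 1 left out. MPI stayed lower in the mutant and past the threshold in all 18 alternatives (limma, DESeq2 or edgeR adjusted p 6.10e-05 to 0.0390). Of 143 named genes that had passed, 120 kept their direction and call in all alternatives in which they were tested, and 23 lost the call in some. Lists that had not passed did so in 21 instances with camera (6 lists) and in 27 with fry (17 lists). Fry values of some of these lists stand in the results. For the others, fry gave adjusted p of 0.00425 for Wnt signalling, 0.00258 for fatty acids and 0.0114 for quiescence (0.134 with the block). It gave 7.77e-04 for matrix proteases, 0.00125 for TGF-beta, 0.0245 for NF-kB and 0.00132 for growth factors. Integrins passed with fry only in the blocked fit (0.0388). The number of rises went from 2866 to 4494 with the replicate block, 4639 with edgeR and the block, 1513 at an adjusted p under 0.01 and 539 at an absolute log2 fold change of at least 1. It was 1738 to 4389 with 1 library left out. Falls went from 2963 to 1799 at an adjusted p under 0.01 and 931 at the fold limit. With both libraries numbered 1 left out, 4984 rose and 4758 fell. Of the fixed lists, 0 passed with an estimated correlation and 19 with fry, with or without the block, which tests each list on its own. Leaving out 1 library at a time gave log2 fold changes of -0.064 to 0.040 for UGP2, -0.012 to 0.047 for CANX, -0.027 to 0.068 for PKM, -0.202 to 0.046 for TNFRSF10B, -0.086 to 0.00329 for MCM7, -0.046 to 0.136 for SPARC, -0.077 to 0.014 for CRTAP, -0.053 to 0.183 for ADAM12, -0.047 to 0.024 for SKI, -3.73e-04 to 0.221 for NFKB2, -0.394 to 0.021 for STAT2, -0.164 to 0.222 for DKK1, -0.012 to 0.117 for EGFR, -0.101 to 0.260 for TIE1 and -0.401 to 0.140 for PTPRC. The sign of the fold change also turned for UGP2 (7.95e-04 with TMM rescaling, 0.00116 with edgeR, 7.19e-04 with edgeR with the replicate block), CANX (-0.018 with upper-quartile rescaling), PKM (-0.00440 with upper-quartile rescaling), SPARC (-0.024 with both libraries numbered 1 left out), ADAM12 (-0.106 with both libraries numbered 1 left out), DKK1 (0.00707 with DESeq2, 0.00707 with the authors' deposited table, 0.019 with edgeR, 0.092 with both libraries numbered 1 left out) and PTPRC (0.00141 with DESeq2, 0.00141 with the authors' deposited table, 0.00965 with edgeR). Among lists that had not passed, camera's direction turned when 1 library was left out, with adjusted p from 0.398 to 0.976 for G2/M, 0.636 to 0.979 for collagen processing, 0.661 to 0.960 for NRF2 targets, 0.503 to 0.877 for glycolysis, 0.471 to 0.930 for pentose phosphate pathway and 0.414 to 0.974 for hypoxia targets. It also turned with DESeq2 (NRF2 targets 0.842, other mesenchymal markers 0.933), the authors' deposited table (NRF2 targets 0.842, other mesenchymal markers 0.933), edgeR (NRF2 targets 0.786, other mesenchymal markers 0.968), edgeR with the replicate block (NRF2 targets 0.934, other mesenchymal markers 0.918) and both libraries numbered 1 left out (glycolysis 0.716, G2/M 0.226, collagen processing 0.864, hypoxia targets 0.864), values being adjusted p. The direction of fry, a test of a list against no change, was opposite to camera's with fry (collagen processing 0.613, NRF2 targets 0.481, other mesenchymal markers 0.895) and fry with the replicate block (collagen processing 0.142, NRF2 targets 0.257, other mesenchymal markers 0.538), also adjusted p. Of the 6 lists that passed, matrix glycoproteins lost the call with the replicate block (0.0548), upper-quartile rescaling (0.0545), a mean of at least 50 (0.193), DESeq2 (0.222), the authors' deposited table (0.222), edgeR with the replicate block (0.178) and an estimated correlation (0.810), mitochondrially encoded genes lost the call with a mean of at least 50 (0.0606), DESeq2 (0.0568), the authors' deposited table (0.0568), edgeR (0.0788), an estimated correlation (0.819) and fry (0.119), G1/S lost the call with an estimated correlation (0.429), YAP/TAZ targets lost the call with an estimated correlation (0.429), interferon-stimulated genes lost the call with an estimated correlation (0.429) and cholesterol synthesis lost the call with an estimated correlation (0.263). Leaving out 1 library gave adjusted p from 0.0129 to 0.114 for matrix glycoproteins and 0.00118 to 0.171 for mitochondrially encoded genes. In the limma fit with camera, the replicate block ended no call of a list except that of matrix glycoproteins, gave one to the TGF-beta list, and changed no other call of a list or of a gene named in the results. Added to edgeR, it ended the call of matrix glycoproteins (0.0300 without it) and gave calls to the NF-kB list (0.00192) and to mitochondrially encoded genes (0.0313). None of the genes and lists whose sign turned had passed on either side. The stricter threshold and the fold limit call fewer genes by construction, and for the other changes the cause was not tested. A higher correlation among members did not end the call of cholesterol synthesis, since its estimate of 0.00933 was below the preset of 0.01. The unadjusted camera p of that list went from 7.05e-07 to 0.00753 between these settings. A call lost with an estimated correlation therefore does not by itself show that members vary together. Depth limits the fold of genes with few reads in a genotype, such as HSD11B1, whose ratio of 206 has an interval from 56.7 to 1706.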

Other observations

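The gene families, the genes named for the libraries numbered 1, and the tests of chance arrangement, of DNA copies and of sequencing depth were chosen only after the result was seen. Of 11 gene families tested together, 4 passed camera at the preset correlation, and none of the 11 passed with an estimated correlation (lowest adjusted p = 0.513). HLA class I and antigen presentation genes were lower: 0 rose and 12 fell of 16 (median -0.44, camera adjusted p = 1.15e-05, and 0.574 with an estimated correlation). HLA-B fell from 14889 ± 685 to 8733 ± 242 and ERAP1, a peptidase that trims peptides for presentation, from 2063 ± 166 to 989 ± 143. HLA genes resemble each other in sequence, so reads between them are uncertain. Of 13 hyaluronan metabolism genes, 6 rose and 0 fell (median 0.19, camera adjusted p = 0.00645, and 0.513 with an estimated correlation). That family holds HAS2 and VCAN, which had been seen among the largest rises. Without them 4 of 11 rose and 0 fell, and the family did not pass (median 0.18, camera adjusted p = 0.0870, and 0.574 with an estimated correlation). TNFAIP6, a hyaluronan-binding protein gene, rose from 64.6 ± 13.5 to 456 ± 40.2.

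Protocadherins were lower, with 2 rises and 14 falls of 38 (median -0.40, camera adjusted p = 0.00723, and 0.574 with an estimated correlation), and PCDH10 fell from 1708 ± 163 to 632 ± 16.6. Many of them lie in a cluster on chromosome 5, where the median of all genes in the position test was -0.17. Replication-dependent histone genes were lower, with 0 rises and 8 falls of 41 (median -0.30, camera adjusted p = 0.00645, and 0.574 with an estimated correlation), and HIST1H1C fell from 2477 ± 615 to 1029 ± 17.4. Most transcripts of such histone genes lack a poly(A) tail, and the libraries were made from poly(A) RNA. Ribosomal protein genes passed only with the replicate block (camera adjusted p = 0.0556 without it and 0.00770 with it). Low levels were more frequent in the mutant: 29 genes had a mean below 10 in mutant and of at least 100 in WT libraries, and 6 the reverse.

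Other splits of the 6 libraries into 3 and 3 were compared with the genotypes, which called 5829 genes with limma (7757 at an unadjusted p under 0.05). The real split was 1 of 10, and 10 splits cannot give a share under 0.05. Each other split mixes the genotypes, so the difference between them adds to the spread within its groups and keeps calls few. Their counts therefore do not show how many genes would be called without a genotype difference. The highest other split called 0 genes, and 2142 at an unadjusted p under 0.05, and it placed both libraries numbered 1 together. The 3 other splits that part all 3 same-numbered pairs, each exchanging 1 pair between the genotypes, also called 0 genes, and 37 to 102 at an unadjusted p under 0.05.

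Neighbouring genes shifted together along the autosomes: over 233 blocks of about 50 genes, the medians of odd-ranked and even-ranked genes correlated at 0.883 across blocks, while 1000 shuffled gene orders reached at most 0.219. That argues against a chance arrangement, and after a trend on GC content and transcript length was removed the correlation was 0.880 (shuffled at most 0.222), which argues against that trend. In the 10 blocks with the largest odd-ranked medians, 216 of the 252 even-ranked genes (85.7%) moved with their block, a share that follows from the correlation already seen and would arise under any shared shift of neighbours, so it does not tell a different number of DNA copies from shared regulation. These blocks lie on chromosomes 1, 5, 6, 7, 11 and 19, with medians of all their genes from -0.51 (chromosome 11, 72106378 to 78046191) to 0.49 (chromosome 7, 75416787 to 92110673), and hold 7.22% of the 4683 changed genes and 4.16% of the 12107 genes in the test. The blocks were chosen for large fold changes in the same data, so a higher share of changed genes in them follows from the choice. Shifts also ran on through consecutive blocks. On chromosome 6 from 109440763 to the last block the medians were 0.38, 0.39 and 0.35, after 0.039 in the block before. On chromosome 7 from 65373799 to the last block they were 0.22 to 0.49, after 0.050. On chromosome 9 from 127424374 to the last block they were -0.27, -0.29 and -0.30, after 0.0090. Other runs ended inside a chromosome. On chromosome 19 from 4343527 to 38975910 the medians were 0.26 to 0.48, before 0.17. On chromosome 11 from 46936689 to 95832693 they were -0.51 to -0.19, before -0.10. On chromosome 5 from 61332273 to 148828687 they were -0.31 to -0.23, before 0.084. Chromosome 15 held no such run (0.00087 to 0.11). DNA was not analysed here, and a different number of DNA copies, shared regulation of neighbours, the mutation itself and differences between cell clones unrelated to it stay open.

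The libraries numbered 1 stood apart in both genotypes: with genotype in the model, 2224 genes were higher and 2846 lower in them (limma), among them the nuclear RNA NEAT1 (log2 difference 1.33) and the BMP target ID1 (-1.13). Sequencing depth is argued against, since they held 33.99 and 33.62 M reads while another library held 34.97 and others fewer. A bias of GC content or transcript length is argued against as well, since the correlation of their deviations was 0.541 after each library's trend was removed and 0.545 before. More unspliced or nuclear RNA in these libraries may be a part: 196 sense intronic genes were higher in them relative to protein-coding genes by a median log2 difference of 0.26 in WT and 0.47 in the mutant. A difference between cultures, such as density or harvest, was not tested, and no biological explanation was tested.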
